A study of Mus musculus with 2 samples.

How the data were processed

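Nuclei were isolated from whole aortas pooled over 3 to 4 mice per group, separated on a density gradient and profiled with droplet-based 3' chemistry with unique molecular identifiers (UMIs), per the labels' protocols. The deposited matrices hold whole-number UMI counts per gene and barcode, made by the authors with Cell Ranger 4.0 on mm10, per the submitters' processing notes, and their barcode lists had already been reduced to called nuclei with at least 500 UMIs. Further steps taken before deposit are not given in the sources used here. Both matrices share 32241 genes, of which 32164 matched a gene of GENCODE vM21 (GRCm38, the assembly also called mm10) by identifier, and positions and gene spans come from that annotation. Counting was not stated to use strand, so antisense and overlapping genes and near-identical copies are uncertain.

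Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9. Barcodes with at least 500 UMIs, at least 300 genes and at most 5% mitochondrially encoded UMIs were kept, which left 8969 of 9067 and 5467 of 5512. Scrublet, run per library in scanpy, set an automatic threshold that called 0 doublets in both libraries, so the highest scores were removed at 0.8% per 1000 nuclei, 644 (7.18%) and 239 (4.37%). The removed barcodes had medians of 6801 and 4486 UMIs. The retained nuclei held 38821639 and 21493184 UMIs, with medians of 1756 and 1308 genes per nucleus.

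Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 31 clusters over both libraries without integration. A cluster was named from markers of 22 cell types. The scoring of those markers was set after seeing the clusters: a mean log2 fold of at least 0.75 and at least 3 markers at 2-fold and 20 CPM. Clusters with a median doublet score of at least 0.1, or smooth muscle markers at 0.5 of their level in smooth muscle or more, stayed unnamed as mixed, and so did clusters with under 0.33 of their library's median UMIs. A cluster with over 90% of its size-adjusted nuclei in 1 library was kept out of the classes, a step added after seeing the clusters. No cluster of a compared class had more markers of another class than of its own among its 10 leading genes. In clusters 0 (smooth muscle), 2 (adipocyte) and 11 (endothelial) those genes held no marker of any class, so the comparison says nothing about them. Class names therefore mean resemblance to the marker set.

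Counts were summed per class and library and given as CPM, counts scaled to an equal total per class and library. Intervals are exact at 95%: Poisson for a sum of counts, Clopper-Pearson binomial for a share, and conditional binomial for a ratio. The interval of a difference in shares combines the bounds of both. They treat UMIs or nuclei as independent and cover counting error only, not the spread between animals. Where no UMI was seen, 3 counts served as the limit in ratios. The median of all genes' log2 ratios was within 0.1 of 0 in every compared class.

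The markers, 33 gene lists, the filters, the tests and the alternatives were chosen before the data were examined, except where the text says otherwise. Classes were compared within genes if they had at least 100 nuclei in each library, which held for 7 classes. A gene was named if it reached 50 CPM in 1 library or more, had a UMI in at least 10% of the nuclei of the library where it was higher, differed by at least 1.5-fold with an interval of the ratio that excluded 1, and had a CPM there of at least 0.3 of that in any other named class. Mitochondrially encoded and ribosomal protein genes, Xist, Tsix, Y-linked genes and unnamed predicted genes were left out. Genes were ranked by the bound of the ratio's interval nearest to 1, and up to 10 higher and 10 lower were taken in the 3 largest classes and 6 and 6 in the others. Of each list, the 2 highest and 2 lowest members at 50 CPM or more could be named as examples, as could markers and Gls2; leading genes of clusters, genes read as RNA of other cells, foam cell genes per nucleus, values per cluster and clock genes were chosen after their values were seen.

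For a gene list the median log2 ratio was taken over members with a mean of at least 20 CPM, if there were at least 5, and its percentile among 10000 random lists of the same size, matched in 20 bins of mean level, describes these libraries only. Of 206 pairs of list and class, 91 medians lay outside the central 95% of their random lists. RNA of other cells was estimated per class as the median, over markers of the other compared classes at 20 CPM or more in the library and at least 2-fold higher in their own class, of their CPM in the class divided by their CPM over all retained nuclei. Markers shared with the class were left out, and for the subtraction that share of the library's profile was taken off, with negative values set to 0. Shares of nuclei with a UMI were also computed after thinning each nucleus to 1000 UMIs.

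The ratios, intervals and list percentiles were tested on simulated counts. In a simulation of smooth muscle with 6666 genes the 95% intervals held the true ratio for 94.9% of genes, and in one of macrophages with 7636 genes for 96.1%. A simulated 2-fold higher level was recovered as 0.99 in smooth muscle (true 0.99) and 0.98 in macrophages (true 1.00), and a 0.5-fold level as -1.04 (true -1.01) and -1.12 (true -1.00). A 0.667-fold level had the right sign in 100% of changed genes in smooth muscle and 92% in macrophages, and 10 of 200 unchanged lists fell outside the central 95% in each. The simulated counts were independent and the unchanged lists were random genes, so the simulation checks the calculation only. It held no RNA of other cells, no effect of gene length and no shared regulation of list members, which real lists may have. Alternatives covered the filter, doublets, cluster resolution, separate clustering, denominators, scaling, weighting of nuclei, thinning, subtraction of RNA of other cells and the level floor of lists.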

Results

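Single-nucleus RNA sequencing was carried out on whole aortas of mice lacking the LDL receptor, a strain that carries high plasma cholesterol and is used to study atherosclerosis. The mice had received a viral vector (AAV) carrying either a scrambled short hairpin RNA or one against Gls2, the liver-type glutaminase, which turns glutamine into glutamate. The title of the series places the defect in hepatic glutaminolysis, so the question addressed is how the vessel wall differs when this step is impaired in the liver. Each group was 1 library made from the pooled aortas of 3 to 4 animals. With 1 library per group no difference has a replicate check, no test between groups was possible, and intervals below cover counting error only. The scrambled shRNA library held 9067 barcodes and 44896629 UMIs, and the Gls2 shRNA library 5512 barcodes and 23204725 UMIs. After filtering and removal of predicted doublets, 8325 and 5228 nuclei were retained, with medians of 3237 and 2177 UMIs per nucleus.

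Gls2 itself (ENSMUSG00000044005, chromosome 10, 128194457 to 128210004 of GRCm38, plus strand, protein-coding) was close to the floor of detection in the aorta. It had 85 UMIs in the scrambled shRNA library, 2.19 CPM (95% Poisson interval 1.75 to 2.71), and 34 UMIs in the Gls2 shRNA library, 1.58 CPM (1.10 to 2.21). The log2 ratio of -0.47 had an interval of -1.09 to 0.12, so a difference was not detectable at this depth. By class it had 28 and 6 UMIs in smooth muscle-like nuclei, 10 and 2 in endothelial-like nuclei, 9 and 0 in adipocyte-like nuclei and 8 and 13 in fibroblast-like nuclei, where the ratio was the other way (log2 ratio 1.54, 0.16 to 3.01). The liver, where the knockdown was placed, was not analysed here, and the labels were therefore not checked by the target. Gls, the kidney-type glutaminase, was far more abundant and near equal over all nuclei, at 265 and 259 CPM, and was lower in endothelial-like nuclei, at 469 and 372 CPM (-0.34, -0.45 to -0.22), and in smooth muscle-like nuclei (-0.13, -0.24 to -0.03). Among the genes of glutamine and glutamate metabolism, the list median lay between -0.23 and 0.12 in the 7 classes compared. The lowest value was in fibroblast-like nuclei, where 10 of 12 measured members were lower and the median stood at percentile 0.54 of 10000 random lists matched on level. Ribosomal protein (-0.51) and mitochondrially encoded (-0.65) transcripts and other short genes (-0.35) were lower in the same nuclei. There the amino acid carrier Slc38a2 stood at 277 CPM in the scrambled shRNA library and 182 CPM in the Gls2 shRNA library.

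Smooth muscle-like nuclei were less abundant in the Gls2 shRNA library, and epithelial-like nuclei with airway genes, T or NK cell-like nuclei and Schwann cell-like nuclei were more abundant. Smooth muscle-like nuclei made up 29.2% of nuclei with the scrambled shRNA (exact binomial interval 28.2 to 30.1%) and 15.1% with the Gls2 shRNA (14.1 to 16.1%). Adipocyte-like nuclei made up 15.4% and 10.8%, a difference of -4.60 percentage points (-5.75 to -3.44). Mesothelial-like nuclei stood at 3.30% and 1.05%. T or NK cell-like nuclei stood at 0.745% (0.571 to 0.954%) and 1.99% (1.63 to 2.41%), B cell-like nuclei at 0.853% and 1.45%, and Schwann cell-like nuclei at 1.24% and 2.05%. The libraries also differed in depth, and the smooth muscle difference of -14.1 points stood at -8.69 at a cluster resolution of 0.5 and at -3.81 when each library was clustered on its own. Endothelial-like nuclei, at 16.5% and 17.3%, and macrophage-like nuclei, at 4.68% and 4.23%, differed by less than their counting error. Fibroblast-like nuclei stood at 8.82% and 10.1%, and with smooth muscle left out of the denominator their difference turned to -0.573 points and that of endothelial-like nuclei to -2.98 points. With the same denominator the difference of macrophage-like nuclei stood at -1.63 points and that of adipocyte-like nuclei at -9.03 points.

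Several clusters belonged almost wholly to the Gls2 shRNA library, and such clusters may stand for what was collected in that library and not for a difference due to the shRNA. Epithelial-like clusters 18 and 22, led by the secretory genes Scgb1a1 and Bpifa1 and by the axonemal dyneins Dnah12 and Dnah3, held 0.432% of nuclei in the scrambled shRNA library and 7.46% in the Gls2 shRNA library. Smooth muscle-like cluster 27, led by Des, Chrm2 and Actg2, held 1 and 46 nuclei. Cluster 10, with leading genes of neurons such as Cntn5, Nrg3 and Syt1, stayed unnamed and held 0.252% and 6.96%. Other unnamed clusters held nuclei of low UMI count (6.87% and 5.22%), mixed markers (7.17% and 9.64%) or no class (0.180% and 0.268%). Of the mixed clusters, 8 held 2.80% and 5.47%, 25 held 0.721% and 1.43%, and 13 held 2.68% and 2.56%. Mixed cluster 26 held 0.973% and 0.172%. Its leading genes include Ppargc1a, Dio2 and Nr4a3, and it was set aside for its doublet score. Nuclei outside the named classes lower the share of every named class in the library they come from. The sources used here do not say whether airway or nerve tissue next to the aorta was collected with it, so every share describes the tissue as collected.

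**Figure D1:**
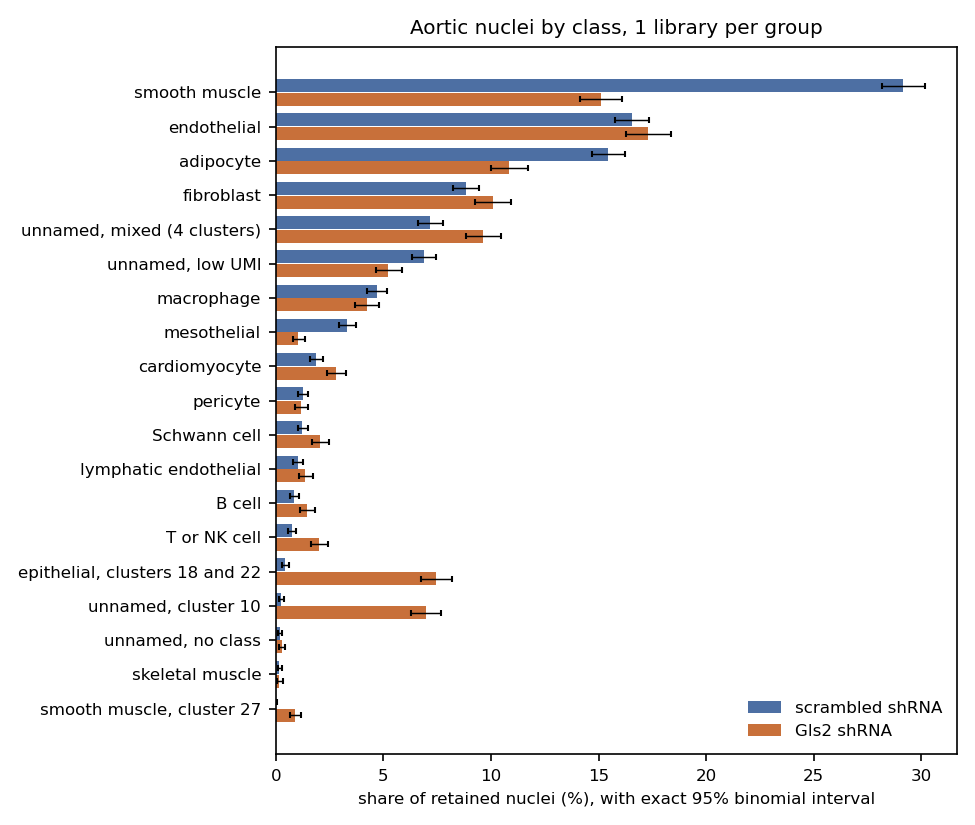
Share of retained nuclei (%) in each class for the scrambled shRNA and Gls2 shRNA libraries, with bars from 0 and exact 95% binomial intervals for counting error. Smooth muscle-like nuclei fill 29.2% and 15.1% of the libraries, and epithelial clusters 18 and 22 fill 0.432% and 7.46%.

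RNA from other cells was present in every class and differed between the libraries. Transcripts of Myh11, the smooth muscle myosin heavy chain, reached 314 CPM in endothelial-like nuclei with the scrambled shRNA and 493 CPM with the Gls2 shRNA, against 4010 and 4146 CPM in smooth muscle-like nuclei. Ppargc1a, a coactivator abundant in brown fat, reached 460 and 178 CPM in the same endothelial-like nuclei. The airway gene Scgb1a1 was at 19.8 and 126 CPM there, and the globin Hbb-bs at 650 and 394 CPM. From markers of other classes, the share of such RNA was put at 19.1% and 17.7% in smooth muscle-like nuclei, 35.3% and 38.3% in endothelial-like nuclei, 14.9% and 21.3% in adipocyte-like nuclei and 40.5% and 45.5% in macrophage-like nuclei.

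In smooth muscle-like nuclei the contractile genes were near equal between the libraries, and genes of respiration, heat shock and lipid storage (19 of 21 lower, median -0.53) were lower with the Gls2 shRNA. The median log2 ratio of 21 contractile genes was 0.00, with Myocd, the master regulator of the contractile state, at 2282 and 2063 CPM. Of 21 respiratory chain genes 20 were lower, with a median of -0.81 at percentile 0 of the random lists, and all 11 measured heat shock genes were lower, with a median of -0.75. Hspb1, a small heat shock protein of muscle, stood at 102 and 40.0 CPM (log2 ratio -1.36, interval -1.62 to -1.10). Mitochondrially encoded transcripts (median -0.93) and ribosomal protein transcripts (-0.55) were lower in the same nuclei.

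Cox8b, a cytochrome oxidase subunit of brown fat and heart, was the lowest of the genes named in smooth muscle-like nuclei, at 63.0 CPM (58.2 to 68.0) and 18.9 CPM (14.6 to 23.9), and the globin Hbb-bs, RNA of red blood cells, was at 296 and 76.8 CPM. The mitochondrial proteins Chchd2 (-1.59), Cox8a (-1.16), Cox6a1 (-1.15) and Etfb (-1.02), the fat-derived Cfd (-1.23), the lipid-binding Dbi (-1.21), the desaturase Scd1 (-1.03) and the chaperone Stip1 (-0.93) were also lower. Cox8b, Cfd and Scd1 are abundant in adipocytes, and Cox8b reached 184 CPM in another class of the scrambled shRNA library. In that library Chchd2, Cox8a, Cox6a1, Etfb and Dbi stood at 80.2, 58.0, 55.6, 51.8 and 88.6 CPM here. They reached 218, 161, 132, 156 and 250 CPM in another class, so they may be RNA of other cells in part. Hspb1 and Stip1 were not higher in another class of at least 100 nuclei. Higher with the Gls2 shRNA were the glutamate receptor Gria1 (0.90, 0.68 to 1.11), the postsynaptic scaffold Dlgap1 (0.78), the dystrophin-associated Sntb1 (0.63, 0.55 to 0.71), the mechanosensitive channel Piezo2 (0.68) and Ldlr (0.67). With the Gls2 shRNA, Dlgap1, Piezo2 and Ldlr stood at 244, 68.1 and 51.5 CPM here, against 605, 227 and 102 CPM in another class. Gria1 and Sntb1 were not higher in another class of at least 100 nuclei. Ldlr was counted at 32.4 and 51.5 CPM in mice whose LDL receptor gene is disrupted, and the counts do not tell disrupted from intact transcripts. Cluster 9 of this class, led by Myl9, Tagln and Acta2, made up 17.2% of it in the scrambled shRNA library and 7.73% in the Gls2 shRNA library. Within clusters 0, 3 and 9 the respiratory chain median was -0.56, -0.70 and -0.44.

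Endothelial-like nuclei had higher Iigp1, Gbp7, Irgm2 and Wars, which interferon induces, and lower respiratory chain genes with the Gls2 shRNA. Iigp1, an interferon-gamma induced GTPase (chromosome 18, 60376027 to 60392634 of GRCm38, plus strand, protein-coding), stood at 237 CPM (223 to 251) and 416 CPM (389 to 444). The related GTPases Gbp7 (log2 ratio 0.80, interval 0.59 to 1.00) and Irgm2 (0.82, 0.55 to 1.10), the interferon-induced tryptophanyl-tRNA synthetase Wars (0.96, 0.68 to 1.23) and the class I antigen-presenting genes H2-Q6 (0.86) and H2-Q7 (0.79) were higher as well. H2-Q6 and H2-Q7 are near copies of each other, so their counts may be split unevenly. Over the whole interferon list 10 of 16 measured members were higher and the median was 0.14, at percentile 99.0 of the random lists, and it stood at 0.030 when each library was clustered on its own and at 0.049 with the mean of CPM per nucleus. Its lower members included H2-D1 at 325 and 262 CPM and Irf1 at 63.1 and 51.3 CPM. The median was 0.35 in cluster 5, led by Gpihbp1 and Cd300lg, 0.19 in cluster 6, led by Bmx and Gja5, 0.47 in cluster 11, led by Frmd5, Vcam1 and the interferon-induced Gbp4, and -0.47 in cluster 15, led by Vwf and Emcn. The log2 ratio of Iigp1 was 0.75 in cluster 5 and 1.13 in cluster 6, but -0.15 (-0.78 to 0.48) in cluster 11 and -0.04 (-0.42 to 0.33) in cluster 15, where Gbp7 (-0.05) and Irgm2 (-0.35) were not higher either. Clusters 5, 6, 11 and 15 held 33.5%, 37.5%, 12.9% and 16.1% of the class in the scrambled shRNA library and 38.3%, 30.3%, 21.5% and 9.96% in the Gls2 shRNA library.

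Tmem45a (1.24), Chn1 (0.92), Samd5 (0.87) and the muscarinic receptor Chrm3 (0.72) were also among the named higher genes of endothelial-like nuclei. With the Gls2 shRNA, Tmem45a, Samd5 and Chrm3 stood at 107, 112 and 405 CPM here, against 110, 116 and 497 CPM in another class. Chn1 was not higher in another class of at least 100 nuclei. Chrm3 is also among the leading genes of smooth muscle-like cluster 27. The named lower genes included the respiratory chain subunits Uqcrb, at 70.9 CPM (63.6 to 79.0) and 17.1 CPM (12.0 to 23.6), Ndufa1 (-1.66), Cox7c (-1.34), Cox6c (-1.25) and Cox5a (-1.23), and Ndufb1 (-1.65), a symbol whose identifier is annotated as a lncRNA. Each of these genes was more abundant in another class of the scrambled shRNA library. Uqcrb, Cox7c, Cox6c and Cox5a stood at 70.9, 192, 237 and 108 CPM here, against 87.6, 340, 350 and 170 CPM there. Of 24 respiratory chain genes 23 were lower, with a median of -0.79. Mitochondrially encoded (-0.64) and ribosomal protein (-0.43) transcripts and other short genes (-0.24) were lower in the same nuclei. The retinoic acid-degrading Cyp26b1 (-1.51), Tmem158 (-1.53) and the calcification inhibitor Mgp (-1.04) were lower, and so was the globin Hbb-bt (-1.39), a transcript of red blood cells that nearly matches Hbb-bs. Endothelial identity genes had a median of -0.02 over 23 members, among them Edn1 at 191 and 106 CPM and Flt1 at 897 and 1022 CPM. All 12 measured LXR targets, among them genes of cholesterol efflux and of lipid synthesis, were lower, with a median of -0.41. Genes of fat were also lower in the same nuclei. Their medians were -0.88 for thermogenic genes (16 of 17 lower) and -0.38 for lipid storage and lipolysis (21 of 24 lower).

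Adipocyte-like nuclei had lower Ppargc1a and higher Acss2, Fasn and Acaca with the Gls2 shRNA, while the list of lipid storage and lipolysis had a median of -0.04 (15 of 24 lower). Of 11 immediate early genes 7 were lower and 4 higher, with a median of -0.42. Ppargc1a (chromosome 5, 51454250 to 51567726 of GRCm38, protein-coding), the coactivator that drives mitochondrial biogenesis and heat production, stood at 7145 and 3626 CPM (log2 ratio -0.98, -1.01 to -0.94). The ratio was -0.74 in cluster 2, which Ppargc1a itself leads, -0.47 in cluster 17, led by Hspa1a and Hmox1, and -1.43 in cluster 12, led by Tmem45b and Cyp2e1, while Ucp1, the uncoupling protein of brown fat, was at 2182 and 2215 CPM in cluster 2. Of 17 thermogenic genes 15 were lower, with a median of -0.23 at percentile 0.435. Within clusters 2, 17 and 12 the thermogenic median was -0.09, -0.20 and -0.30, at percentiles 4.93, 4.66 and 0.090, and only that of cluster 12 lay outside the central 95% of random lists. Cluster 2 held 73.6% of the class in the scrambled shRNA library and 48.7% in the Gls2 shRNA library, cluster 12 held 16.4% and 26.5%, and cluster 17 held 9.95% and 24.9%. Acss2, which makes acetyl-CoA from acetate, stood at 448 CPM (433 to 463) and 925 CPM (883 to 968). Fasn and Acaca, enzymes of fatty acid synthesis, were at 324 and 500 CPM and at 2304 and 3398 CPM.

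The growth hormone receptor Ghr (0.89), the sortilin-type receptor Sorcs2 (2.04), Prune2 (1.78), Pgm3 (1.28), Eepd1 (1.05), Capn2 (1.02), Sntb1 (0.96) and Grk5 (0.95) were also among the named higher genes of adipocyte-like nuclei. With the Gls2 shRNA, Prune2, Grk5, Sntb1, Capn2 and Eepd1 stood at 140, 340, 385, 163 and 114 CPM there. In the class where each was highest they reached 323, 834, 598, 222 and 137 CPM. Ghr, Sorcs2 and Pgm3 were not higher in another class of at least 100 nuclei. Contractile smooth muscle genes as a list were higher in the adipocyte-like nuclei (median 0.95, 18 of 19 members). The immediate early receptors Nr4a3 (-1.26) and Nr4a1 (-0.91), the phosphatase gene Dusp1 (-1.21), the mitophagy receptor Bnip3 (-1.25), the thermogenic regulator Irf4 (-1.09), Trim2 (-1.05) and Polr3h (-1.05) were lower. Of 15 clock genes 4 were higher and 11 lower, with a median of -0.08 at percentile 10.8. Arntl was higher (0.98, 0.76 to 1.20) and Per3 (-1.19, -1.53 to -0.87) and Bhlhe40 (-1.35) were lower, while Per1 (-0.13), Nr1d1 (0.12), Cry1 (-0.10) and Nfil3 (-0.07) differed little. With the Gls2 shRNA, Arntl stood at 126 CPM here against 209 CPM in fibroblast-like nuclei. The respiratory chain median was -0.32 and that of ribosomal protein genes 0.08.

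Fibroblast-like nuclei had lower Sfrp4 and Tnfaip6 and lower immediate early genes with the Gls2 shRNA. Sfrp4, a secreted modulator of Wnt signalling, stood at 163 CPM (147 to 181) and 62.0 CPM (49.1 to 77.2), and Tnfaip6, a hyaluronan-binding protein induced by inflammation, at 80.8 CPM (69.5 to 93.3) and 29.0 CPM (20.4 to 40.0). The lysosomal protease Ctsl (-1.67), Ppp2r2b (-1.48), Tmem100 (-1.28) and Cox6b1 (-1.55) were also lower. In the scrambled shRNA library Ctsl, Ppp2r2b and Cox6b1 stood at 82.5, 170 and 52.7 CPM here, against 91.7, 220 and 149 CPM in another class. Higher were Lhfpl2 (1.28), the cytokine signalling inhibitor Socs2 (1.03), the ephrin receptor Ephb2 (0.95), Myo1d (0.83, 0.67 to 0.99), Gse1 (0.81) and the basement membrane collagen Col4a6 (0.81). Myo1d, Col4a6 and Socs2 reached 1233, 1190 and 201 CPM in another class, and the contractile list was higher in these nuclei (0.46). Of 16 immediate early genes 14 were lower, with a median of -0.44, and 10 of 11 genes of modulated smooth muscle were lower, with Fn1 at 543 and 315 CPM. Genes of fat (thermogenic -0.53, lipid storage and lipolysis -0.49), mitochondrially encoded transcripts (-0.65) and ribosomal protein transcripts (-0.51) were lower in the same nuclei. Fibrillar collagens differed little, with a median of -0.12 that turned to 0.10 when nuclei were thinned to 1000 UMIs.

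Macrophage-like nuclei had lower levels of genes of lipid-laden macrophages with the Gls2 shRNA, and genes of fat were lower in the same nuclei. The lipid-laden list was also lower in the other 6 classes, with medians of -0.74 in smooth muscle-like (9 of 9 lower, and -0.27 with the mean of CPM per nucleus), -0.60 in cardiomyocyte-like, -0.51 in Schwann cell-like, -0.46 in fibroblast-like, -0.36 in endothelial-like and -0.28 in adipocyte-like nuclei. In macrophage-like nuclei Ppargc1a stood at 1873 and 534 CPM. Thermogenic genes had a median of -1.04 there (15 of 16 lower), between -1.90 and -0.62 over the alternatives. Genes of lipid storage and lipolysis had one of -0.77 (23 of 24 lower), between -1.65 and -0.54. All 15 measured members of the lipid-laden list with UMIs in both libraries were lower, with a median log2 ratio of -1.09 at percentile 0 of the random lists. Gpnmb, a glycoprotein of foam cells, had 271 UMIs (211 CPM, 186 to 237) and 2 UMIs (4.31 CPM, 0.522 to 15.6). Atp6v0d2, a subunit of the lysosomal proton pump, had 151 UMIs and none (interval 0 to 7.95 CPM). With the 2 members that lacked UMIs in the Gls2 shRNA library set at 3 counts, the median was -1.15. The cathepsin Ctsl (chromosome 13, 64359337 to 64370890 of GRCm38) stood at 91.7 CPM (75.9 to 110) and 15.1 CPM (6.07 to 31.1), and Lyz2, the macrophage lysozyme, at 194 CPM (171 to 220) and 60.3 CPM (40.1 to 87.2). The cholesterol exporters Abca1, at 986 and 444 CPM, and Abcg1, at 141 and 53.9 CPM, were the lowest LXR targets among those at 50 CPM or more, a list with a median of -0.71.

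Of the 13 measured markers that define the class 8 were lower and 5 higher, with a median of -0.12. F13a1 was at 2148 and 2297 CPM, Mrc1 at 1315 and 1444 CPM and Csf1r at 246 and 276 CPM, while C1qc was at 92.5 and 38.8 CPM (-1.25, -2.06 to -0.53) and Cybb at 96.4 and 66.8 CPM. Cd68 and Trem2, under the level at which a marker was measured, had 24 and 3 UMIs and 17 and 2 UMIs. UMIs of Gpnmb came from few nuclei, 20 of 390 (5.13%, 3.16 to 7.81%) with the scrambled shRNA and 2 of 221 (0.905%, 0.110 to 3.23%) with the Gls2 shRNA, at median depths of 2073 and 1214 UMIs. After thinning to 1000 UMIs the shares were 5.11% and 0.794%, with 116 and 95 shallower nuclei left out. In endothelial-like nuclei, which should lack the gene, the unthinned shares were 1.38% and 0.553% at median depths of 2280 and 1537 UMIs, so the share with the Gls2 shRNA was not above background. The 151 UMIs of Atp6v0d2 came from 12 of 390 nuclei (3.08%, 1.60 to 5.31%), and after thinning 2.19% of nuclei held one. Endothelial-like nuclei held a UMI of Atp6v0d2 in 8 of 1377 (0.581%) and 3 of 904 (0.332%), unthinned. Cd38 (-1.72), Mthfs (-1.79), Rgs2 (-1.78) and Zfhx4 (-1.83) were also among the named lower genes of the class, of which Rgs2 and Zfhx4 reached 291 and 294 CPM in another class against 118 and 107 CPM here. The adipocyte genes Fabp4, Lpl, Cd36 and Plin2 belong to the lipid-laden list and were more abundant in adipocyte-like nuclei.

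**Figure D2:**
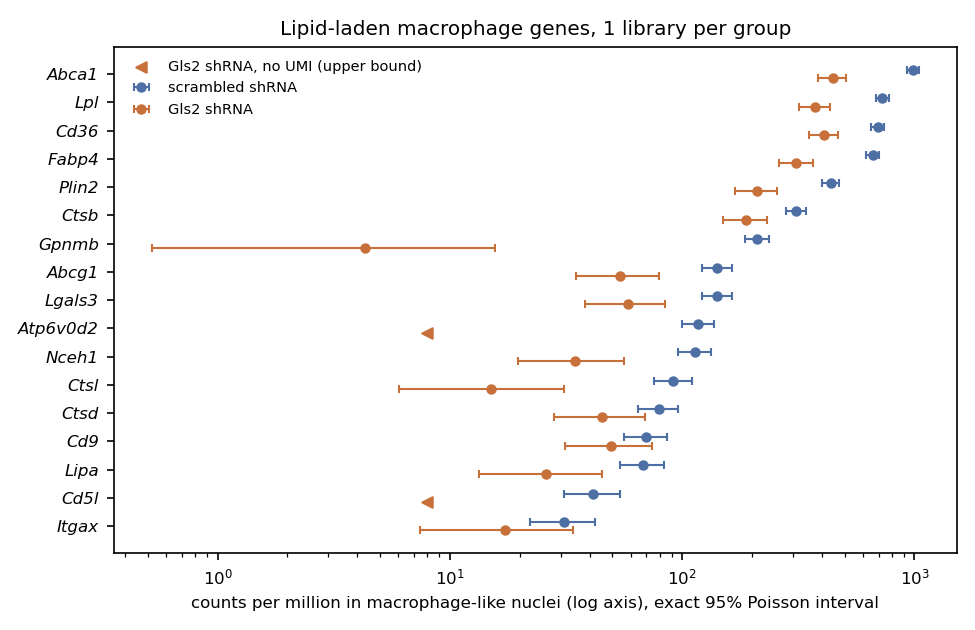
Levels of lipid-laden macrophage genes in macrophage-like nuclei, in CPM on a log axis, for the scrambled shRNA and Gls2 shRNA libraries, with exact 95% Poisson intervals for counting error and arrows at the interval's upper bound of 7.95 CPM where no UMI was counted. All plotted genes lie lower in the Gls2 shRNA library, from Abca1 at 986 and 444 CPM to Itgax at 31.1 and 17.2 CPM.

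The 6 higher genes named in macrophage-like nuclei were Mylk4 (2.65), Cap2 (2.25), Myh11 (1.48), Col4a6 (1.61), Klf12 (1.71) and Slco3a1 (1.65). Each was more abundant in another class, with Myh11 at 1267 CPM here against 4146 CPM in smooth muscle-like nuclei of the Gls2 shRNA library. The contractile list had a median of 1.31 in these nuclei and 19 of 20 members were higher; it stood at 0.73 when predicted doublets were kept.

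Cardiomyocyte-like nuclei, 155 and 146 in number, had higher Hcn1 and Cacna2d2 and lower globins with the Gls2 shRNA. The pacemaker channel gene Hcn1 stood at 15.7 CPM (9.13 to 25.1) and 393 CPM (347 to 443), and the calcium channel subunit Cacna2d2 (2.71), Kctd8 (2.33), Scd4 (3.02), Il31ra (2.05) and Tenm2 (6.34, 3.79 to 11.67, from 1 and 50 UMIs) were higher too. Tenm2 is among the leading genes of the unnamed cluster 10, whose first leading gene, Cntn5, stood at 6.45 and 28.3 CPM in these nuclei (2.13, 0.82 to 3.63). Sln, sarcolipin of atrial muscle, was lower (-1.48), with Ndufb3 (-1.93) and the globins Hbb-bs (-3.14), Hbb-bt (-3.40), Hba-a1 (-1.77) and Hba-a2 (-1.98), which are near copies in pairs. In Schwann cell-like nuclei, 103 and 107 in number, Pcdh15 (3.88), Cacna2d3 (3.27), Klhl13 (2.03), Chrm3 (1.94) and Meis1 (1.69) were higher, and Etfdh (-2.54), Mapk3 (-2.67), Ugp2 (-1.70), Fabp4 (-1.36), Cox8b (-2.08) and Hbb-bs (-1.31) lower. Chrm3, also a leading gene of cluster 27, stood at 178 CPM in Schwann cell-like nuclei with the Gls2 shRNA against 497 CPM in another class. Egr1 was higher at 2.41 but stood at -0.007 when predicted doublets were kept. RNA of other cells was put at 57.1% and 58.4% of these cardiomyocyte-like profiles and at 59.0% and 66.9% of the Schwann cell-like ones.

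Across classes, respiratory chain genes were lower in all 7, with medians from -0.84 in Schwann cell-like nuclei to -0.32 in adipocyte-like nuclei. Mitochondrially encoded transcripts had medians from -0.93 to -0.08 and ribosomal protein transcripts from -0.55 to 0.08, in both cases with adipocyte-like nuclei at the upper end. Short genes outside these lists, with a span under 5 kb, had medians of -0.29 in smooth muscle-like, -0.24 in endothelial-like, -0.35 in fibroblast-like and 0.09 in adipocyte-like nuclei. Contractile smooth muscle genes were higher in endothelial-like (0.43), fibroblast-like (0.46), adipocyte-like (0.95) and macrophage-like (1.31) nuclei, in which RNA of other cells was counted as well. Xist was at 1381 and 1271 CPM over all retained nuclei, and the Y-linked Uty had 8 and 2 UMIs.

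**Figure D3:**
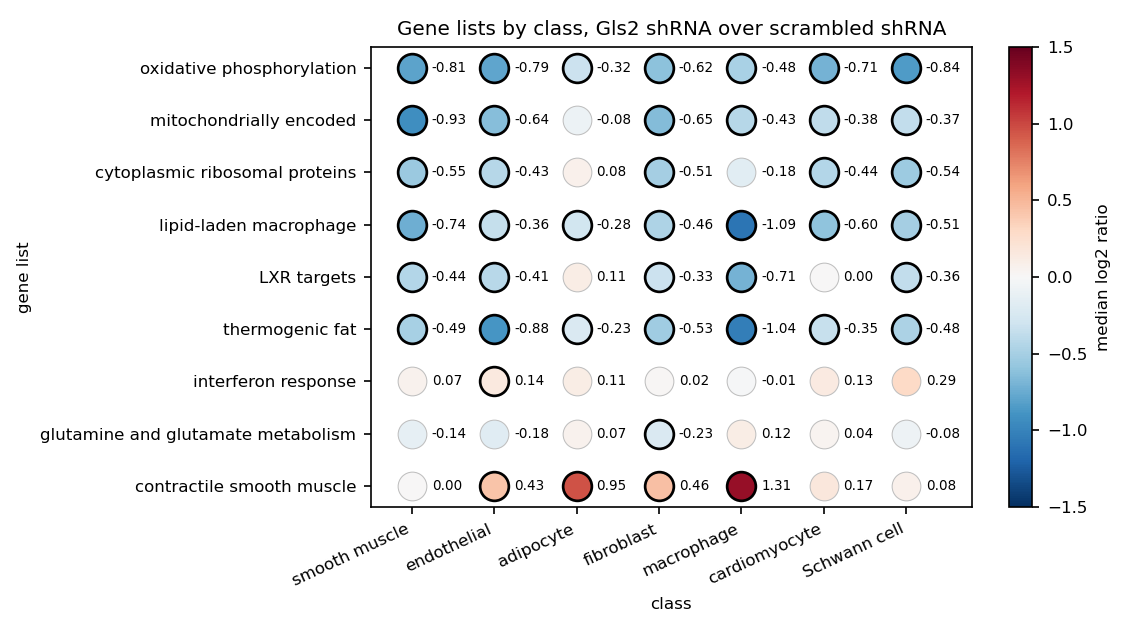
Median log2 ratio (Gls2 shRNA over scrambled shRNA) of the measured members of 9 gene lists in 7 classes, given by colour and printed beside each point, with a black outline where the median lies outside the central 95% of random lists matched on level. Respiratory chain medians run from -0.84 to -0.32, and the lipid-laden macrophage list is lowest in macrophage-like nuclei at -1.09.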

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

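Keeping clusters mostly of 1 library out of the classes was decided after the clusters were seen, and the opposite directions of lists in different classes given here were not tested. Nuclei found almost wholly in the Gls2 shRNA library entered no class. Epithelial-like clusters 18 and 22, with secretory and ciliary airway genes, made up 7.46% of its retained nuclei. Unnamed cluster 10, with the neuronal genes Cntn5, Nrg3 and Syt1, made up 6.96%, and smooth muscle-like cluster 27, with Des, Chrm2 and Actg2, made up 0.880%.

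Some gene lists lay outside the central 95% of random lists in opposite directions in different classes. Cholesterol synthesis genes had a median log2 ratio of -0.31 in smooth muscle-like nuclei and 0.41 in fibroblast-like nuclei, where 5 members were measured. Heat shock genes stood at -0.75 in smooth muscle-like nuclei and 0.39 in adipocyte-like nuclei. Hsp90aa1, the chaperone, was at 168 and 122 CPM in the former and at 163 and 276 CPM in the latter. The heat shock gene Hspa1a is a leading gene of adipocyte-like cluster 17, which held 9.95% and 24.9% of its class. It is also one of smooth muscle-like cluster 9, which held 17.2% and 7.73%. Over the alternatives, among them clusters weighted alike, the smooth muscle heat shock median stayed between -0.835 and -0.621. Fibrillar collagen genes stood at -0.12 in fibroblast-like nuclei and 0.66 in adipocyte-like nuclei, and genes of the endothelial-to-mesenchymal transition at -0.067 in smooth muscle-like nuclei and 0.47 in adipocyte-like nuclei. Markers of other cells were higher in the same adipocyte-like nuclei, with the contractile list at 0.95, Myh11 at 191 and 442 CPM, the fibroblast gene Lama2 at 28.0 and 80.2 CPM, and RNA of other cells put at 14.9% and 21.3%. Resident macrophage genes stood at -0.33 in smooth muscle-like nuclei and 0.37 in fibroblast-like nuclei. Several of these directions turned with the processing: resident macrophage genes in fibroblast-like nuclei stood between -0.081 and -0.56 under 4 alternatives, cholesterol synthesis there at -0.033 and -0.021 under 2, fibrillar collagen there at 0.099 and 0.017 under 2, and the endothelial-to-mesenchymal list in smooth muscle-like nuclei at 0.011 under 1.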

How the results depend on the processing

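The alternatives that put mixed or one-library clusters back in a class, weighted clusters alike or left out nuclei with foam cell genes were chosen after seeing the data, and the cause was not tested for any value here. Shares are differences in percentage points, list and gene values are log2 ratios, all Gls2 shRNA against scrambled shRNA. With each library clustered on its own, shares stood at -3.81 (smooth muscle), -3.22 (adipocyte) and 5.20 (epithelial); lists at 0.011 (endothelial-to-mesenchymal transition, smooth muscle), -0.57 and -0.96 (mitochondrially encoded, smooth muscle and fibroblast), 0.72 and 1.01 (contractile, adipocyte and macrophage), -0.10 (resident macrophage, fibroblast), and in macrophages -1.59 (lipid-laden), -1.65 (lipid storage) and -1.90 (thermogenic fat). At Leiden resolution 0.5, smooth muscle stood at -8.69, epithelial at 4.23, and in macrophages contractile at 1.49, lipid-laden at -1.43 and thermogenic fat at -1.33. At resolution 2, endothelial share was -0.595 and thermogenic fat -0.55 (endothelial) and -0.62 (macrophage). With doublets kept, smooth muscle share was -10.2, thermogenic fat -0.49 and mitochondrially encoded -0.30 in endothelial nuclei, contractile 0.73 in macrophages and Egr1 -0.007 in Schwann cells. With every deposited barcode, smooth muscle share was -12.0 and contractile in macrophages 0.95. Outside the largest class, shares were -2.98 (endothelial), -9.03 (adipocyte), -0.573 (fibroblast), -1.63 (macrophage), -3.42 (mesothelial) and 8.18 (epithelial), and among named clusters 2.86 (endothelial), 2.63 (fibroblast) and 9.07 (epithelial). With mixed clusters in the class of their markers, fibroblast share was 3.94, contractile in adipocytes 0.69 and cholesterol synthesis in fibroblasts -0.033. With clusters weighted alike, mitochondrially encoded in smooth muscle was -0.49 and contractile in adipocytes 0.57. With members at 5 CPM or more, cholesterol synthesis in fibroblasts was -0.021. With at least 1000 UMIs and at most 1% mitochondrial, resident macrophage in fibroblasts was -0.081, contractile in macrophages 1.46 and mitochondrially encoded in cardiomyocytes 0.007. With nuclei thinned to 1000 UMIs, mitochondrially encoded was -0.31 (endothelial), fibrillar collagen 0.099 (fibroblast) and -0.028 (cardiomyocyte), resident macrophage -0.23 (fibroblast) and contractile 0.91 (macrophage), and median genes per nucleus, lower in most classes before, differed by -11 (smooth muscle), 1 (adipocyte), 21 (cardiomyocyte) and 30 (Schwann cell). With the mean of CPM per nucleus, thermogenic fat was -0.50 and mitochondrially encoded -0.28 (endothelial), fibrillar collagen 0.017 (fibroblast) and -0.27 (cardiomyocyte), contractile 0.77 (macrophage) and lipid storage 0.15 (Schwann cell). With RNA of other cells subtracted, lipid-laden in smooth muscle (-0.74 in the report) was -0.90, against -0.27 with the mean of CPM per nucleus, -0.31 with each library clustered on its own, -0.31 with clusters weighted alike and -0.42 with one-library clusters in their class, resident macrophage in fibroblasts -0.56, and thermogenic fat -1.53 (macrophage) and 0.074 (cardiomyocyte); this alternative gave a value for 177 of 206 lists and 87 of 104 named genes, since members reached 0. Respiratory chain genes stayed between -0.91 and -0.51 in smooth muscle, between -1.02 and -0.72 in endothelial and between -0.79 and -0.56 in fibroblast nuclei, the lipid-laden list in macrophages between -1.59 and -0.91, and the interferon list in endothelial nuclei between 0.030 and 0.22. No paired analysis was possible because each group has 1 library. Depth limits what low genes show: the ratio of Gls2, at 2.19 and 1.58 CPM, had an interval of -1.09 to 0.12.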

Other observations

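The test of adipocyte RNA for the respiratory chain genes and the value without nuclei holding Gpnmb or Atp6v0d2 were chosen only after the results were seen. Stress and redox genes were lower in several classes of the Gls2 shRNA library. In fibroblast-like nuclei 6 of 7 genes of the integrated stress response were lower, with a median log2 ratio of -0.82, among them its transcription factor Atf4 at 55.3 and 29.0 CPM (-0.93). The median was -0.29 with nuclei thinned to 1000 UMIs and -0.33 with members at 5 CPM or more, and ribosomal protein transcripts (-0.51) and other short genes (-0.35) were lower in the same nuclei. Genes of hypoxia and redox had a median of -0.31 in smooth muscle-like and endothelial-like nuclei and -0.54 in macrophage-like nuclei. Sod2, the mitochondrial superoxide dismutase, stood at 80.9 and 40.2 CPM in endothelial-like nuclei and at 84.7 and 28.0 CPM in macrophage-like nuclei, and was more abundant in adipocyte-like nuclei, at 154 and 131 CPM.

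Ldlr transcripts were higher over all retained nuclei, at 24.0 and 39.5 CPM (0.72, 0.58 to 0.86), and stood at 23.4 and 50.7 CPM in adipocyte-like nuclei and at 20.6 and 44.7 CPM in fibroblast-like nuclei. In adipocyte-like nuclei cholesterol synthesis genes had a median of 0.31 at percentile 99.1, with the sterol dehydrogenase Nsdhl at 52.6 and 85.3 CPM. The elastic fibre genes there had a median of 0.71, with all 5 measured members higher, among them elastin (Eln) at 216 and 353 CPM and Ltbp1 at 79.0 and 147 CPM, both more abundant in smooth muscle-like nuclei. In macrophage-like nuclei the 5 measured cell cycle genes were higher, with a median of 0.93 from few UMIs, such as 35 and 24 UMIs of Anln. Over all retained nuclei the medians were -0.28 for clock genes, -0.30 for immediate early genes, -0.34 for heat shock genes, -0.04 for glucocorticoid response genes and 0.12 for nuclear-retained RNA. These pooled medians move with the mix of classes in each library as well as with levels within classes. The heat shock list, for example, stood at -0.75 in smooth muscle-like and 0.39 in adipocyte-like nuclei.

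Respiratory chain, mitochondrially encoded and ribosomal protein transcripts were lower in most classes, except that in adipocyte-like nuclei the mitochondrially encoded (-0.08) and ribosomal (0.08) lists, and in macrophage-like nuclei the ribosomal list (-0.18), lay inside the central 95% of random lists matched on level. Matched on gene span as well, the mitochondrially encoded list lay under the 2.5th percentile only in smooth muscle-like (1.13) and endothelial-like (2.445) nuclei. The ribosomal list did so only in smooth muscle-like (0.86) and Schwann cell-like (1.91) nuclei. In the other classes these lists did not stand apart from genes of like level and span. RNA of adipocytes carried into other droplets could not be judged. After a share of the whole library's profile was subtracted, the respiratory chain median over the other 6 classes was -0.74. In macrophage-like nuclei the respiratory chain median moved from -0.48 to -0.33. That subtraction does not single out RNA of adipocytes, and thermogenic genes in macrophage-like nuclei went from -1.04 to -1.53 after it. Less cytoplasmic RNA in the Gls2 shRNA library stays open: other short genes had a median of -0.22 over the 7 classes, though 0.09 in adipocyte-like and -0.01 in cardiomyocyte-like nuclei, where respiratory chain genes were also lower. Lower expression of the respiratory chain genes also stays open, as the list lay under the 2.5th percentile of lists matched on level and gene span in 7 of 7 classes. Each of these may contribute, and a difference due to the Gls2 shRNA was not tested apart from the library.

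Lipid-laden macrophage genes were lower in macrophage-like nuclei. The list lay at percentile 0 among lists matched on level and gene span, so gene span alone did not account for it. Gene span reflects cytoplasmic RNA only indirectly, and the list lay under the 2.5th percentile in every compared class. Less cytoplasmic RNA therefore stays open. Adipocyte RNA was argued against by a median of -1.28 without the members more abundant in adipocyte-like nuclei. Fewer lipid-laden macrophages among the nuclei and lower expression of these genes per nucleus cannot be told apart, because both would place the list, at -0.97 relative to the macrophage markers, below them. Without nuclei holding a Gpnmb or Atp6v0d2 UMI the list, then without those genes, still stood at -0.91. A lipid-laden nucleus may hold no UMI of either gene at this depth, so that value does not tell these explanations apart.

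Clock genes of opposite phase lay apart, with Arntl and Npas2 higher and Per3 lower in adipocyte-like nuclei, although the list as a whole had a median of -0.08 there and Npas2 was more abundant in fibroblast-like (425 and 580 CPM) than in adipocyte-like nuclei (35.2 and 92.4 CPM). So was Arntl, at 188 and 209 CPM against 63.8 and 126 CPM. The arm with Arntl stood above the arm with Per3 in 7 of 7 classes, which tissue taken at different times of day could give. The arm with Per3 was itself not lower in fibroblast-like nuclei (0.10) and was near 0 in macrophage-like (-0.02) and cardiomyocyte-like (-0.05) nuclei. The classes come from the same libraries and share RNA of other cells, so they are not separate observations. After RNA of other cells was subtracted, the difference had a median of 0.0695 over the 6 classes other than adipocytes, but the classes went both ways, with smooth muscle at 0.32 (0.39 before), Schwann cell at 1.40 (0.62 before) and cardiomyocyte at -0.54 (0.15 before). In adipocyte-like nuclei it was 1.15, and 1.31 after subtraction. A different time of day, RNA of adipocytes in the other classes and a difference within the fat cannot be told apart here, because of that split and because the labels used here give no time of collection.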
